A study of Mus musculus with 30 samples.

How the data were processed

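Nucleus accumbens RNA of male Hdac5 knockout mice and wildtype littermates was measured on 30 Illumina Mouse-6 bead arrays, each hybridised with RNA pooled from 4 mice. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on RNeasy Micro columns, amplified linearly with an Ambion kit and labelled with biotin, so each array had 1 colour. Samples were grouped by the genotype, treatment and replicate number in their titles: wildtype saline, wildtype cocaine, knockout saline and knockout cocaine, with 6 biological pools each. The design text describes a set of 12 arrays (8 pools and 4 technical arrays) and a later set of 18 arrays from newly treated mice (16 pools and 2 technical arrays), called cohort 1 (replicates 1 and 2) and cohort 2 (replicates 3 to 6) here. Each pool came from different mice, so the spread between pools holds both biological and technical variation. The 6 technical arrays were left out of the main tests because the labels do not say which pool each repeats.

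The records are of several kinds. The per-array files hold 1 intensity per probe on a linear scale, per the file headers. Set against the bead-level files, this deposited intensity equals the mean of the probe's beads plus a constant for each of the 2 strips of the array, with no normalization between arrays. The bead-level files hold the deposited intensity of each bead, per the file headers. The value table of the series holds values on a log2 scale that the authors deposited; its columns rank probes as the per-array files do, every column has a median of 0, a background was removed, and the direction rises with intensity. How that background was estimated and which further scaling was applied stay unknown. The image analysis and normalization software were not given in the sources used here, and neither was a genome build. No detection p was held, and the files name no chip.

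For 25 of the 30 samples the 3 records held the same array. For 5 samples (wildtype cocaine pool 5, knockout saline pool 5, knockout cocaine pool 5 and technical array 2 of each cocaine group) the value table and the bead-level files matched each other but held an array that the per-array files list under another of these 5 names. The per-array files were the main source, as fixed beforehand. Results with the other records, and without the 3 pools concerned, are among the alternatives.

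An array carried 1756751 to 2116984 beads, with a median of 35 to 44 beads per probe and no fewer than 4. The median probe intensity was 144.7 to 216.0 in cohort 1 and 49.5 to 65.56 in cohort 2, so the cohorts differed in brightness. Within cohort 1 it was 144.7 to 155.0 for replicate 2 and the cocaine technical arrays. For replicate 1 and the saline technical arrays it was 186.1 to 216.0, and the main fit has no term for this difference. The number of pools limits the precision. Intensities of the 44505 probes common to all arrays were background-corrected with normexp (offset 50), put on the log2 scale and quantile-normalized over the 30 arrays with limma 3.58.1 in R 4.3.3. A probe was kept if it lay above the median probe of its array in at least 6 of the 24 pools, which left 25593 probes (12495 genes). Gene names came from the platform annotation, in which 28482 of the 44505 probes have 1 symbol, 11 have several and 16012 are not named here. The gene identifiers of 28427 named probes were found in the mouse reference table (GRCm38.p6), and no symbol changed through it. That table served only for names and for which genes neighbour Hdac5.

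Each probe was fitted with limma (lmFit and eBayes, 8.41 prior and 19 residual degrees of freedom) on the 24 pools of all groups, with a coefficient for each group and a term for the cohort. The 7 contrasts were knockout against wildtype after saline, after cocaine and averaged, cocaine against saline in wildtype, in knockout and averaged, and the interaction (the cocaine effect in knockouts minus that in wildtypes). P-values were adjusted by Benjamini-Hochberg over the probes kept, and a probe with an adjusted p under 0.05 is described as called. Differences are log2 values with their standard error (SE). A pool shows the direction of a difference if it lies on that side of the mean of the comparison group, after removing the cohort effect. Where a probe was not above the median probe in some or all pools of a group, a bound was computed as the bright group's mean against the higher of the dim probe and the median probe of each array.

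The groups, tests, gene lists and alternatives were chosen before the data were examined, except where stated. Named genes were Hdac5, Tacr1 and, in each contrast, the 10 called probes with the largest rise and the 10 with the largest fall that carry 1 symbol. Where fewer than 5 passed in a direction, the smallest unadjusted p filled up to 5, and these are given as not passing. Up to 4 members of each gene list with the smallest p were added. Tests worked on probes, and other probes of a named gene are given where they bear on the result. Other called genes are named as the rest of a count.

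Gene lists were tested with camera of limma (preset inter-gene correlation of 0.01, the brightest probe per gene, at least 4 measured genes), adjusted over 28 lists and 7 contrasts (196 tests), and again with an estimated correlation. Of 29 lists fixed, the sex-linked label check had fewer than 4 kept genes and was not tested. The lists covered class IIa histone deacetylases and MEF2 factors, other histone deacetylases and sirtuins, histone acetyltransferases and methyltransferases, immediate early genes, genes linked to chronic cocaine, tachykinins and their receptors, medium spiny neurons, interneurons, neuropeptides, glutamate receptors, GABA receptors, potassium channels, synaptic genes, actin and spine regulators, glucocorticoid-induced genes, clock genes, chaperones, interferon and inflammatory genes, oligodendrocytes, astrocytes, microglia, endothelial and mural cells, blood cells, choroid plexus, cortical excitatory neurons, septum, thalamus and hypothalamus, oxidative phosphorylation and cytosolic ribosomal proteins. Whether calls gather around Hdac5 was tested with a two-sided Fisher's exact test of the genes within 10 Mb against all other genes.

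The fit was tested on simulated data with noise drawn independently for each probe. For each contrast, 50 of the 25593 probes were changed by each of 1.2-, 1.5-, 2- and 3-fold, all in the same data. The strong changes ease the adjusted threshold for the weaker ones. The shares recovered may therefore be too high for contrasts in which few probes change. Of probes changed 1.5-fold, 100% were recovered for knockout against wildtype after saline, 96% after cocaine, 94% for cocaine in wildtypes, 96% for cocaine in knockouts and 88% for the interaction; of those changed 1.2-fold, the shares were 38%, 32%, 34%, 18% and 10%. In the averages over treatments and over genotypes, 96% and 100% of probes changed 1.5-fold and 68% and 78% of those changed 1.2-fold were recovered.

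Alternatives were no background correction, median scaling, the value table, an own bead summary (beads within 3 median absolute deviations), no filter and a stricter one (14935 probes), no cohort term, each cohort alone, the replicate number as a block, all 30 arrays, only the groups compared, a trended robust prior, array weights, an unadjusted p under 0.05 with a fold over 1.3, each pool left out in turn, and, for the lists, estimated correlation, fry and the mean over all probes of a gene. Leaving out the 3 pools whose records disagree, leaving each pool out of the list and neighbour tests, and the lists in cohort 1 alone and in each cohort with the probes chosen on all pools were added after seeing the data. Other alternatives that used the brightest probe of a gene chose it anew on their own pools and values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.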

Results

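The nucleus accumbens, a ventral striatal region of the brain's reward circuit, was profiled in male mice lacking Hdac5 and in their wildtype littermates. Hdac5 encodes a class IIa histone deacetylase, a signal-regulated repressor of transcription that binds MEF2 factors. Mice received 7 daily intraperitoneal injections of saline or of 20 mg/kg cocaine, which blocks dopamine reuptake, and tissue was taken 24 h after the last injection. The stated aim was to find expression differences between the genotypes that could bear on how differently they behave after cocaine. Each of the 4 combinations of genotype and treatment had 6 pools of 4 mice, measured on bead arrays that carried 1756751 to 2116984 beads each. A further 6 technical arrays were left out of the main tests. They entered the normalization, the per-array values of Hdac5 and Prm1, the check of the sample records and the alternative that used all arrays. The pools came in 2 separately treated cohorts, which held 2 and 4 pools of every group.

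Hdac5 separated the genotypes on all 30 arrays. Its probe 6370139 read 13.0 to 14.82 times the array's median probe on the 6 wildtype arrays of cohort 1 and 1.5 to 1.75 times on the 6 knockout arrays. In cohort 2 it read 14.85 to 18.91 times on the 9 wildtype arrays and 2.01 to 2.72 times on the 9 knockout arrays. A second probe, 2370035, read 2.84 to 3.35 and 1.62 to 2.46 times the median probe on wildtype arrays of cohorts 1 and 2, and 0.94 to 1.09 and 0.85 to 1.13 times on knockout arrays. In the fit averaged over treatments, Hdac5 fell by 2.88 ± 0.06 (SE, 12 pools per genotype; adjusted p = 1.30e-23) on the first of these probes, a 7.35-fold difference, and by 1.27 ± 0.07 on the other, each in 12 of 12 knockout pools. On the latter 7 of 12 knockout pools lay above the median probe, so its difference was at least 2.34-fold. The differences of probe 6370139 were -3.13 within cohort 1 and -2.75 within cohort 2. The files do not say which part of Hdac5 the knockout allele lacks or where each probe lies. Hdac5 checks the genotype of an array only, and the treatment labels have no such check, which matters for the 5 samples whose deposited records disagree.

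**Figure D1:**
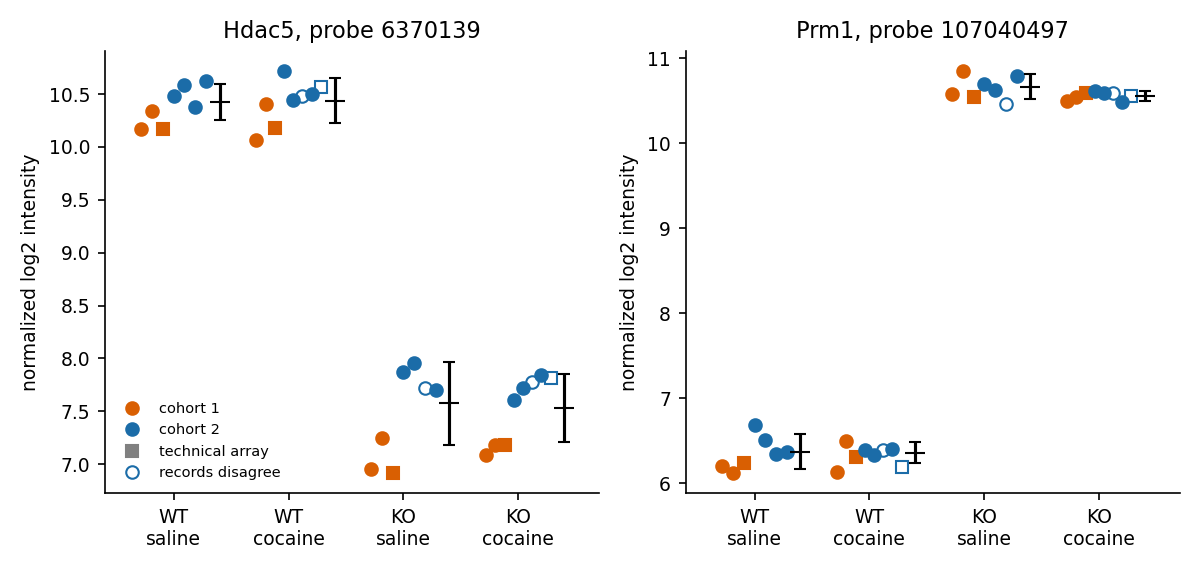
Normalized log2 intensity (vertical axis) of Hdac5 (left) and Prm1 (right) by genotype and treatment; circles are pools, squares technical arrays, open symbols the 5 samples whose deposited records disagree, orange cohort 1 and blue cohort 2, with the mean ± SD of 6 pools beside them. Hdac5 lay between 10.07 and 10.72 on wildtype arrays and between 6.91 and 7.95 on knockout arrays, and Prm1 between 6.12 and 6.69 and between 10.45 and 10.85.

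After saline, the knockout accumbens differed from the wildtype in 10 named genes, 4 higher and 6 lower. Prm1, which encodes the sperm DNA-packing protein protamine 1, rose by 4.29 ± 0.08 on the log2 scale (SE, n = 6 pools per group; adjusted p = 4.52e-25); only 2 of the 6 wildtype pools lay above the array's median probe, which makes the difference at least 17.9-fold. Mpp3, a membrane-associated guanylate kinase scaffold, rose by 0.91 ± 0.07 and 0.71 ± 0.07 on its called probes, Cuedc1, a ubiquitin-binding domain protein, by 0.67 ± 0.13 (adjusted p = 0.0305), and Lgi2, a secreted leucine-rich repeat protein, rose by 0.41 ± 0.07 (adjusted p = 0.00248). Besides Hdac5, Krt12, a keratin of the cornea, fell by 1.88 ± 0.23 and by 1.82 ± 0.24 on its probes. Rapgefl1, a guanine exchange factor-like protein, fell by 1.09 ± 0.21 and Gkn3, a gastrokine of brain arteries, fell by 0.63 ± 0.12, each with an adjusted p of 0.0305. Fcrls, a scavenger receptor of microglia, fell by 0.91 ± 0.18 and Dgke, a diacylglycerol kinase, fell by 0.48 ± 0.10, each with an adjusted p of 0.0404. All of these showed their direction in 6 of 6 pools.

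With limma, 17 of 25593 probes were called after saline, 8 higher and 9 lower, of which 13 carry a gene name. At an unadjusted p under 0.05 there were 1115 probes (4.36%), a smaller share than that threshold gives when nothing differs. Splits of the pools within cohorts that ignored genotype gave as many in 66 of 100. Within cohorts 1 and 2 the differences were 4.55 and 4.17 for Prm1, 0.92 and 0.91 for the stronger Mpp3 probe, 0.61 and 0.71 for Cuedc1, 0.38 and 0.42 for Lgi2, and -1.18 and -2.23 for Krt12. They were -1.65 and -0.54 for Fcrls, -0.72 and -0.58 for Gkn3, and -0.75 and -0.35 for Dgke. Rapgefl1 differed by -0.26 in cohort 1, which did not pass there at an unadjusted p of 0.05, and by -1.51 in cohort 2. Prm1, Mpp3, Lgi2, Hdac5 and Krt12 were called in all 24 fits that left out 1 pool. Cuedc1 and Rapgefl1 were each lost in 8 of these fits (adjusted p of up to 0.139, without knockout saline pool 3), and Gkn3 in 8 (up to 0.142, without knockout saline pool 1). Fcrls was lost in 11 (up to 0.196, without wildtype saline pool 1) and Dgke in 15 (up to 0.193, without knockout saline pool 2). Another Fcrls probe differed by -0.26, another Dgke probe by 0.13 and the remaining Mpp3 probe by 0.16, none of which passed.

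After cocaine, the comparison closest to the stated aim, 13 named genes differed between the genotypes, 4 higher and 9 lower. The 4 higher genes were those of the saline comparison. Prm1 rose by 4.19 ± 0.08 (SE, n = 6 pools per group; adjusted p = 8.57e-25), or at least 17.0-fold, with 1 of 6 wildtype pools above the median probe. Cuedc1 rose by 0.92 ± 0.13 (adjusted p = 1.91e-04), Mpp3 by 0.86 ± 0.07 and 0.76 ± 0.07, and Lgi2 by 0.32 ± 0.07 (adjusted p = 0.0465). Hdac5 fell by 2.90 ± 0.09, Krt12 fell by 1.83 ± 0.24 and 1.80 ± 0.23, and Rapgefl1 fell by 1.46 ± 0.21 (adjusted p = 2.82e-04). The uncharacterised 4933427D14Rik fell by 1.07 ± 0.16 (adjusted p = 5.44e-04). Fxr2, an RNA-binding relative of the fragile X protein, fell by 0.73 ± 0.14 (adjusted p = 0.0277), Ndel1, a regulator of the dynein motor, fell by 0.60 ± 0.11 (adjusted p = 0.0114), and Dgke fell by 0.54 ± 0.10 (adjusted p = 0.00793). Chd3, a chromatin remodeller, fell by 0.45 ± 0.09 (adjusted p = 0.0213). Arhgap15, a Rac GTPase-activating protein, fell by 0.46 ± 0.08 (adjusted p = 0.0118); its probe lay above the median probe in 0 of 6 knockout pools, so the difference was at least 1.18-fold. The direction was seen in 6 of 6 pools for each of these genes other than Chd3, for which pools were not counted and which was singled out after its value was seen.

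With limma, 24 probes were called after cocaine, 10 higher and 14 lower, 16 of them with a gene name, and 1056 (4.13%) had an unadjusted p under 0.05. Within cohorts 1 and 2 the differences were 4.20 and 4.19 for Prm1, 0.85 and 0.96 for Cuedc1, 1.02 and 0.78 for the stronger Mpp3 probe, and 0.41 and 0.28 for Lgi2. Among the lower genes they were -1.07 and -2.21 for Krt12, -0.88 and -1.75 for Rapgefl1, -0.68 and -1.26 for 4933427D14Rik, -0.45 and -0.67 for Ndel1, -0.72 and -0.46 for Dgke, -0.38 and -0.48 for Chd3, and -0.30 and -0.53 for Arhgap15. Fxr2 differed by -0.46 in cohort 1, which did not pass there at an unadjusted p of 0.05, and by -0.87 in cohort 2. Of the 24 fits that left out 1 pool, Lgi2 was lost in 20 (adjusted p of up to 0.219, without knockout cocaine pool 2) and Fxr2 in 7 (up to 0.139, without knockout cocaine pool 4). Arhgap15 was lost without wildtype cocaine pool 4 or 6 or knockout cocaine pool 3 (up to 0.0610), and Ndel1 without knockout cocaine pool 3, 4 or 6 (up to 0.0552). Other probes of Ndel1, Arhgap15, Dgke and Fxr2 differed by -0.05, -0.02, 0.08 and -0.24, and the remaining Mpp3 probe by 0.16, none of which passed.

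Averaged over both treatments, 31 genes differed between knockout and wildtype, 14 higher and 17 lower. Prm1 rose by 4.24 ± 0.06 (SE, n = 12 pools per genotype; adjusted p = 4.95e-29; at least 17.4-fold), Mpp3 by 0.89 ± 0.05 and 0.74 ± 0.05, and Cuedc1 by 0.80 ± 0.09 (adjusted p = 4.18e-06), each in 12 of 12 pools. Lgi2 rose by 0.36 ± 0.05 in 12 of 12 pools (adjusted p = 3.21e-05) and by 0.63 ± 0.12 in 11 of 12 on another probe (adjusted p = 0.0207, and 0.0507 without wildtype cocaine pool 1). Smaller rises were those of Rgs4, which shortens G protein signals (0.37 ± 0.07, adjusted p = 0.0115, 11 of 12 pools), the neuritin relative Nrn1l (0.33 ± 0.07, 0.0224), Asb16 (0.32 ± 0.07, 0.0337) and the chemokine Cxcl12 (0.27 ± 0.06, 0.0328), the last 3 in 12 of 12 pools; another Cxcl12 probe differed by -0.10 and did not pass. Krt12 fell by 1.84 ± 0.16 (at least 3.52-fold, with 9 of 12 knockout pools above the median probe), Rapgefl1 fell by 1.28 ± 0.15 (adjusted p = 5.49e-06), Fcrls fell by 0.82 ± 0.13 (8.69e-04) and 4933427D14Rik fell by 0.80 ± 0.11 (1.54e-04). Fxr2 fell by 0.53 ± 0.10 (0.0145), Gkn3 fell by 0.52 ± 0.09 (0.00168) and Dgke fell by 0.51 ± 0.07 (5.71e-05). All of these falls were seen in 12 of 12 pools. Other probes of Dgke, Fxr2 and Fcrls differed by 0.10, -0.26 and -0.24, and the remaining Mpp3 probe by 0.16, none of which passed.

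The rest of the 31 genes lay outside the 10 probes with the largest change in each direction. Lsm12, Slc35f4, Osbpl3, Otof, Prom1 and Entpd3 rose by 0.26 to 0.24. Ndel1 fell by 0.49 and Chd3 fell by 0.35, while Ifitm1, Rdm1, Abca5, Crybb1, Mif4gd, P2ry13 and Gosr1 differed by -0.32 to -0.23, all called. Of these, P2ry13, an ADP receptor, and Crybb1 are, like Fcrls, known as microglial genes in the brain and were singled out after their values were seen; their differences were -0.25 ± 0.05 (adjusted p = 0.0207) and -0.28 ± 0.05 (adjusted p = 0.0145).

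The averaged differences within cohorts 1 and 2 were 4.38 and 4.18 for Prm1, -1.13 and -2.20 for Krt12, -0.57 and -1.63 for Rapgefl1, and -1.23 and -0.61 for Fcrls. In cohort 1, Rgs4 differed by 0.19, Asb16 by 0.16 and Fxr2 by -0.38, none of which passed there at an unadjusted p of 0.05. In cohort 2 they differed by 0.46, 0.41 and -0.61. In the 24 fits that left out 1 pool, Asb16 was lost in 16 (adjusted p of up to 0.0779, without knockout saline pool 4). Cxcl12 was lost in 15 (up to 0.0782, without wildtype cocaine pool 1) and Nrn1l in 7 (up to 0.0567, without wildtype saline pool 1). limma called 46 of 25593 probes here, 23 higher and 23 lower, and 1151 (4.50%) had an unadjusted p under 0.05. Of the 11 called probes not named here, 104060685 and 103870239 rose at least 5.69-fold and 2.49-fold, with 0 and 8 of 12 wildtype pools above the median probe, and 102060075 and 106040463 fell by 0.59 ± 0.10 and 0.57 ± 0.04.

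The probes called between the genotypes after saline and after cocaine overlapped. Of the 17 and 24 probes called, 15 were shared, all with the same sign, against 0.016 for independent lists of these sizes. The 2 comparisons have no pools in common. Both came from 1 fit that shares each probe's variance and cohort term, so their lists are not independent. For the 46 probes of the averaged comparison, limma's interaction gave a smallest adjusted p of 1, with 2 of 46 at an unadjusted p under 0.05; in simulated data it recovered 10% of probes changed 1.2-fold, so small differences between treatments were not detectable. Across 12495 genes the differences after saline and after cocaine had a Pearson r of 0.288 and a Spearman rho of 0.066, and without the called genes 0.014 and 0.06; genes are not independent replicates. The median SE was 0.0763 per treatment.

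**Figure D2:**
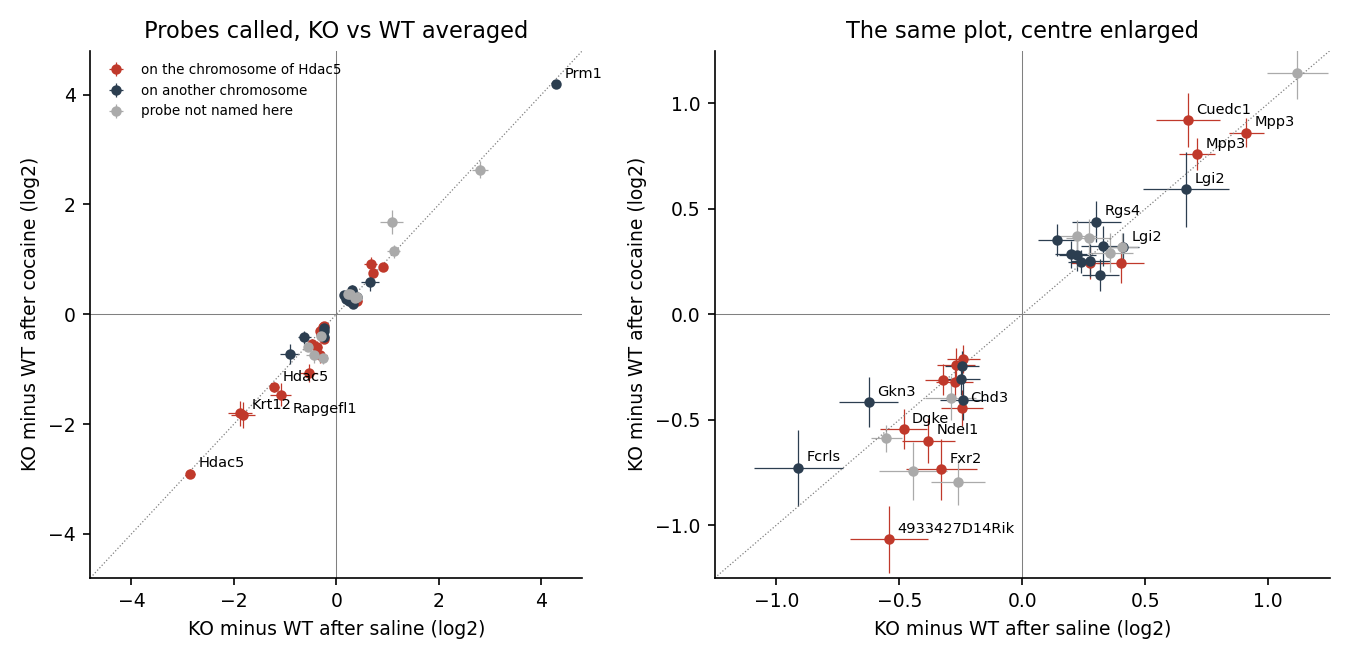
Log2 difference between knockout and wildtype after saline (horizontal axis) and after cocaine (vertical axis) for the 46 probes called in the averaged comparison, with the centre enlarged on the right; bars are SE, red marks genes on the chromosome of Hdac5, dark blue other named genes and grey probes not named here. The probes ran from Hdac5 at -2.85 and -2.90 to Prm1 at 4.29 and 4.19.

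Genes that differed between the genotypes gathered near Hdac5. With Hdac5 itself left out, 7 of 257 measured genes within 10 Mb of it were called (2.72%), against 23 of 12212 other genes (0.188%), an odds ratio of 14.8 (two-sided Fisher's exact test, p = 1.98e-06). The 7 genes were Abca5, Asb16, Krt12, Lsm12, Mpp3, Rapgefl1 and Rdm1. Another 8 lay on the same chromosome farther away: 4933427D14Rik, Chd3, Cuedc1, Dgke, Fxr2, Gosr1, Mif4gd and Ndel1. The remaining 15 of 11421 genes (Prm1, Lgi2, Fcrls, Gkn3 and Rgs4 among them) lay on other chromosomes. The odds ratio was 95.7 in cohort 1 alone (2 of 257 and 1 of 12212 genes, Fisher's exact p = 0.00125) and 19.3 in cohort 2 alone (Fisher's exact p = 1.5e-04). With 1 pool left out it ran from 11.0, without knockout cocaine pool 1, to 23.0, without knockout cocaine pool 5. Of these genes on the chromosome of Hdac5, 7 had several probes kept. Other probes of Krt12, Mpp3 and Fxr2 moved the same way at an unadjusted p under 0.05. Those of Chd3 (-0.03), Dgke (0.10), Lsm12 (-0.06) and Ndel1 (-0.05) did not. The other Fxr2 probe (-0.26) was not called (limma adjusted p = 0.221).

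Microglia markers were lower in the knockout accumbens by camera with its preset correlation. Of 11 measured genes, 9 were lower after saline (mean log2 difference -0.12), 10 after cocaine (-0.10) and 10 in the average (-0.11), with camera adjusted p-values of 1.45e-04, 2.20e-04 and 1.88e-07. With an estimated correlation the adjusted p was 0.522, 0.537 and 0.219, so none of these calls held. In the average, 5 of 11 genes passed when adjusted over the list alone and 0 over all probes: the complement genes C1qc (-0.18 ± 0.04, adjusted p = 0.00279, 11 of 12 pools), C1qb (-0.23 ± 0.06, 11 of 12) and C1qa (-0.19 ± 0.06, 10 of 12), the actin-binding Aif1 (-0.18 ± 0.05, 11 of 12) and the Fc receptor chain Fcer1g (-0.19 ± 0.07, 10 of 12). After saline Aif1 (-0.26, 6 of 6 pools) and C1qb (-0.26, 5 of 6) passed over the list alone, and after cocaine C1qc (-0.23, 6 of 6). The list means in cohorts 1 and 2 were -0.10 and -0.14 after saline (adjusted p = 0.123 and 2.65e-04), -0.10 and -0.10 after cocaine (0.0417 and 0.0135) and -0.10 and -0.12 in the average (0.00784 and 3.69e-06). With the series value table the cocaine call was lost (adjusted p = 0.0548).

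Lists of glial, ribosomal and neuronal genes were also called by camera between the genotypes, in 5 calls that did not hold with an estimated correlation (adjusted p = 0.952 for each). Oligodendrocyte markers, the genes of myelin-forming glia, were lower in the knockout after saline (mean -0.09, 14 of 18 genes lower, adjusted p = 0.0106) and in the average (-0.06, 15 of 18, 0.0102), with Mal at -0.22, Mog at -0.20 and Ugt8a at -0.17 after saline; none passed over the list alone. Ribosomal protein genes were lower after saline (mean -0.04, 42 of 53 lower, 0.0209); Rps19 (-0.39 ± 0.09, 6 of 6 pools) was the member that passed when adjusted over the list alone (adjusted p = 0.00423). Immediate early genes were higher after saline (mean 0.07, 20 of 26 higher, 0.0237), led by Fos (0.37 ± 0.13, 6 of 6) and Egr2 (0.27), with 0 passing over the list alone. In the same comparison interneuron genes (mean 0.12, 12 of 16 higher, 0.0731) and cortical excitatory markers (mean 0.16, median 0.06, 11 of 17, 0.361) were also higher, neither of them called. Markers of cortical excitatory neurons were lower after cocaine (mean -0.30, median -0.08, 12 of 17 lower, 0.0120), led by the glutamate transporter Slc17a7 (-1.39 ± 0.57), Nrn1 (-0.88 ± 0.32), Ccn2 (-0.79) and Neurod2 (-0.76), again with 0 passing over the list alone.

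These list calls depended on single pools and cohorts. The oligodendrocyte means were -0.04 and -0.08 in cohorts 1 and 2 after saline (adjusted p = 0.612 and 0.0345) and 0.01 and -0.08 in the average (0.959 and 0.00148). Fits within a cohort chose the brightest probe of a gene anew, so their means need not bracket that of all pools. With the probes chosen on all pools, the oligodendrocyte means were -0.08 and -0.09 after saline (0.311 and 0.0208) and -0.01 and -0.08 in the average (0.968 and 6.09e-04). These calls were lost in 5 and 2 of 24 fits with 1 pool left out (adjusted p of up to 0.286 and 0.130, both without wildtype saline pool 4). The ribosomal means were -0.04 in each cohort (0.447 and 0.0628), with the call lost in 5 fits (up to 0.185, without knockout saline pool 1). The immediate early means were 0.07 in each cohort (0.133 and 0.158), with the call lost in 6 (up to 0.184, without the same pool). The cortical means after cocaine were -0.40 and -0.25 (2.19e-05 and 0.266), and the call was lost without wildtype cocaine pool 2 or 4 or knockout cocaine pool 3 or 6 (up to 0.278). Splits of the pools within cohorts that ignored genotype called as many lists as the 4, 2 and 2 found after saline, after cocaine and in the average in 33, 63 and 58 of 100 draws.

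For cocaine in wildtype mice, camera called 3 lists and limma no single probe. With an estimated correlation none of the list calls held (adjusted p = 0.769, 0.57 and 0.952 for the immediate early, glucocorticoid and ribosomal lists). Immediate early genes, which neurons switch on within minutes of activity, were higher (mean 0.11, 21 of 26 higher, camera adjusted p = 2.18e-04). Fos (0.53 ± 0.13), the synaptic Arc (0.46) and the phosphatase Dusp1 (0.30) passed when adjusted over the list alone (adjusted p = 0.0053, 0.0053 and 0.00928), each in 6 of 6 pools. Markers of neurons of other regions moved the same way without being called: cortical excitatory markers (mean 0.17, median 0.07, 13 of 17 higher, adjusted p = 0.207) and markers of septum, thalamus and hypothalamus (mean 0.07, 9 of 14, 0.226). Glial lists shifted too without being called. Relative to the cohort mean, astrocyte markers averaged -0.03 in saline and 0.03 in cocaine pools. Oligodendrocyte markers averaged 0.06 and -0.0045, and microglia markers 0.08 and 0.03. Glucocorticoid-induced genes were higher (mean 0.10, 14 of 19, 0.00401), with the lipid droplet gene Plin4 (0.59 ± 0.14, adjusted p = 0.00434) and Sult1a1 (0.24) passing over the list alone, each in 6 of 6 pools. Ribosomal protein genes were lower (mean -0.05, 45 of 53 lower, 2.20e-04), with 0 passing over the list alone, Rps19 at -0.17, Rps15 at -0.13, Rps16 at -0.11 and Rps24 at 0.15.

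limma called 0 of 25593 probes for cocaine in wildtypes (smallest adjusted p = 0.830), and 1169 (4.57%) had an unadjusted p under 0.05. The genes nearest the threshold were Rcan3 (0.26), Plin4, Polr3a (0.28), Paqr8 (0.27) and Fos on the higher side and Ccdc103 (-0.32), Cd3d (-0.28), Tnni1 (-0.37), Tfap4 (-0.31) and Dmtf1 (-0.35) on the lower, none of which passed, with 6 of 6 pools showing each direction. After cocaine, 1 of 6 pools lay above the median probe for Cd3d and for Tfap4, 0 of 6 for Dmtf1 and 5 of 6 for Ccdc103, and after saline 5 of 6 for Tnni1 and 4 of 6 for Dmtf1, so these sizes are not reliable. Other probes differed by 0.06 and 0.10 for Rcan3, by 0.01 and -0.06 for Polr3a and by -0.03 to 0.09 for Dmtf1. Within cohorts 1 and 2 the difference was 0.57 and 0.59 for Plin4 and 0.91 and 0.34 for Fos. The immediate early mean was 0.25 in cohort 1 (adjusted p = 4.44e-10) and 0.03 in cohort 2 (0.827), the glucocorticoid mean 0.13 and 0.08 (0.00441 and 0.252) and the ribosomal mean -0.06 and -0.05 (0.0689 and 0.0132). These camera p-values used the preset correlation, with 2 and 4 pools per group, and no estimated correlation was run within a cohort. With the series value table the ribosomal call was lost (adjusted p = 0.188); the list mean was 0.01 there, still below the median of all probes, which was 0.07 in that table.

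For cocaine in knockout mice, camera called 3 lists and limma no single probe. Again no list call held with an estimated correlation (adjusted p = 0.57, 0.952 and 0.952 for the glucocorticoid, medium spiny and cortical lists). Glucocorticoid-induced genes were higher (mean 0.09, 15 of 19, camera adjusted p = 0.00401), of which the kinase Map3k6 (0.31, 6 of 6 pools) passed when adjusted over the list alone (adjusted p = 0.0479). Genes of medium spiny neurons, the principal cells of the accumbens, were higher (mean 0.07, 25 of 29, 0.00401), with Ppp1r1b (0.19), Pdyn (0.17), Gng7 (0.16) and Ppp1r2 (0.13) at the smallest p and 0 passing over the list alone. Cortical excitatory markers were lower in the same pools (mean -0.28, median -0.09, 11 of 17, 0.0197), with Slc30a3 at -1.05, Nrn1 at -0.83 and Neurod2 at -0.75, none passing.

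limma called 0 of 25593 probes for cocaine in knockouts (smallest adjusted p = 1.0), with 880 (3.44%) at an unadjusted p under 0.05. Sugct (0.53 ± 0.11), Tgds (0.55), Gpx6 (0.39), the clock gene Per2 (0.34) and Sorcs1 (0.26) were nearest the threshold on the higher side, and Car4 (-0.30), Arhgap15 (-0.33), Phlda3 (-0.46), Sstr2 (-0.34) and Parp9 (-0.26) on the lower; none passed, and 6 of 6 pools showed each direction, with 0 of 6 knockout cocaine pools above the median probe for Arhgap15. After saline, 4 of 6 knockout pools lay above the median probe for Sugct and for Gpx6 and 5 of 6 for Tgds, so the sizes for these 4 genes are not reliable. Another Per2 probe differed by 0.01, another Tgds probe by -0.05, another Arhgap15 probe by -0.15 and the other Sorcs1 probes by 0.02 and 0.03. Within cohorts 1 and 2 the differences were 0.29 and 0.65 for Sugct and 0.67 and 0.18 for Per2. The medium spiny mean was 0.02 and 0.09 (adjusted p = 0.594 and 0.00462), the cortical mean -0.05 and -0.40 (0.834 and 0.0132) and the glucocorticoid mean 0.14 and 0.07 (7.93e-04 and 0.144). The medium spiny call was lost without knockout saline pool 2 or 3 (up to 0.305). The glucocorticoid call was lost without knockout saline pool 1 or knockout cocaine pool 5 (up to 0.108). The cortical call was lost without knockout saline pool 1, 3 or 6 or knockout cocaine pool 3 or 6 (up to 0.201). Across 12495 genes the cocaine effects in wildtypes and knockouts had a Pearson r of -0.024 and a Spearman rho of 0.028.

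The interaction asked whether cocaine acted differently in the knockout. Arhgap15 came closest among single genes, with a cocaine effect lower in knockouts by -0.66 ± 0.12 (log2; adjusted p = 0.149; -0.48 and -0.75 in cohorts 1 and 2), and did not pass. Its probe lay above the median probe in 2 of 6 wildtype saline and 0 of 6 knockout cocaine pools, so the size of this difference is not reliable. Another Arhgap15 probe differed by -0.22 and did not pass. By camera 4 lists were called, none of which held with an estimated correlation (adjusted p = 0.952 for each). The cocaine effect on immediate early genes was lower in knockouts than in wildtypes (mean -0.13, 19 of 26 lower, adjusted p = 0.00401), with Fos at -0.61 ± 0.18, Nr4a2 at -0.73, Arc at -0.40 and Dusp1 at -0.28. That on ribosomal protein genes was higher (mean 0.07, 46 of 53, 0.00147; Rps19 0.36, Rps15 0.17, Rps24 -0.21). So was that on oxidative phosphorylation genes, which make up the mitochondrial respiratory chain (mean 0.06, 43 of 51, 0.0493; Atp5j 0.16, Ndufb3 0.12). That on cortical excitatory markers was lower (mean -0.45, median -0.15, 11 of 17, 0.00418), led by Nrn1 (-1.43 ± 0.45), Neurod2 (-1.15), Tmem178 (-0.47) and Nptx1 (-0.43). No member of these lists passed when adjusted over the list alone. Lists not called here shifted as well, relative to the cohort mean. Interneuron genes averaged -0.06 and 0.04 in wildtype saline and cocaine pools, against 0.07 and -0.05 in knockout pools. Markers of septum, thalamus and hypothalamus averaged -0.04 and 0.03, against 0.04 and -0.03. Medium spiny genes averaged 0.0024 and 0.0033, against -0.04 and 0.03. Astrocyte markers averaged -0.03 and 0.03, against 0.0013 and -0.01.

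limma called 0 of 25593 probes for the interaction, and 917 (3.58%) had an unadjusted p under 0.05. Other genes near the threshold were Dmtf1 (0.57), Ccdc187 (0.38), Entpd4 (0.47), Adam12 (0.29) and Arhgap10 (0.41), and Zfp346 (-0.38), Celsr3 (-0.38), Tyms (-0.47) and Syt13 (-0.47), none of which passed. Probes of Dmtf1, Ccdc187, Entpd4, Celsr3 and Tyms lay below the median probe in some pools of these groups, Dmtf1 in all pools of wildtype cocaine and knockout saline, so their sizes are not reliable either. Other probes differed by -0.05 to 0.11 for Dmtf1, by 0.06 and -0.04 for Adam12, by 0.11 and 0.09 for Arhgap10 and by 0.25 for Entpd4. They differed by -0.02, -0.01 and -0.27 for Zfp346, by -0.12 for Celsr3 and by -0.30 for Tyms. List means within cohorts 1 and 2 were -0.21 and -0.08 for immediate early genes (adjusted p = 1.34e-05 and 0.660), 0.07 in each for ribosomal genes (0.133 and 0.0239), -0.35 and -0.52 for cortical genes (0.0107 and 0.0568) and 0.02 and 0.07 for oxidative phosphorylation genes (0.648 and 0.0628; 0.0348 in cohort 2 with the probes chosen on all pools). The immediate early call was lost without wildtype cocaine pool 1 (0.108), the cortical call without wildtype cocaine pool 2 (0.0629), and the oxidative phosphorylation call in 15 of 24 such fits (up to 0.259, without wildtype cocaine pool 1). As many lists as the 4 found here were called in 23 of 100 splits of the pools, and for cocaine in wildtypes, in knockouts and averaged in 43, 43 and 65.

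Averaged over genotypes, glucocorticoid-induced genes were higher after cocaine (mean 0.09, 16 of 19 higher, camera adjusted p = 5.34e-05), in cohort 1 (0.13, 1.34e-05) and in cohort 2 (0.07, 0.0239). With an estimated correlation the list's adjusted p was 0.219, so the call did not hold. Plin4 (0.44 ± 0.10, adjusted p = 0.00208, 11 of 12 pools), Map3k6 (0.24, 11 of 12), Sult1a1 (0.20, 12 of 12) and the clock and stress gene Per1 (0.20, adjusted p = 0.0402, 10 of 12) passed when adjusted over the list alone and 0 over all probes. Immediate early genes were higher (mean 0.05, 19 of 26, 0.0171), a call that did not hold with an estimated correlation (adjusted p = 0.952), with 0 passing over the list alone and Arc (0.26), Fos (0.23), Klf4 (0.20) and Dusp1 (0.16) each higher in 10 of 12 pools. The means were 0.15 (1.83e-07) and -0.01 (0.827) in cohorts 1 and 2. The call was lost in 6 of 24 fits with 1 pool left out (up to 0.204, without knockout saline pool 2). limma called 0 probes (smallest adjusted p = 0.397) and 1110 (4.34%) had an unadjusted p under 0.05. Sugct (0.41 ± 0.08), Per2 (0.32 ± 0.07, and 0.05 on another probe), Pnrc2 (0.50) and Vwf (0.30) were nearest on the higher side with Plin4, and Tnni1 (-0.29), Tmem81 (-0.21), Phlda3 (-0.34), Cntn6 (-0.22) and Fam120b (-0.18) on the lower. None passed, and Sugct and Tnni1 lay below the median probe in some saline pools, so their sizes are not reliable. Other Fam120b probes differed by -0.08 to 0.02.

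**Figure D3:**
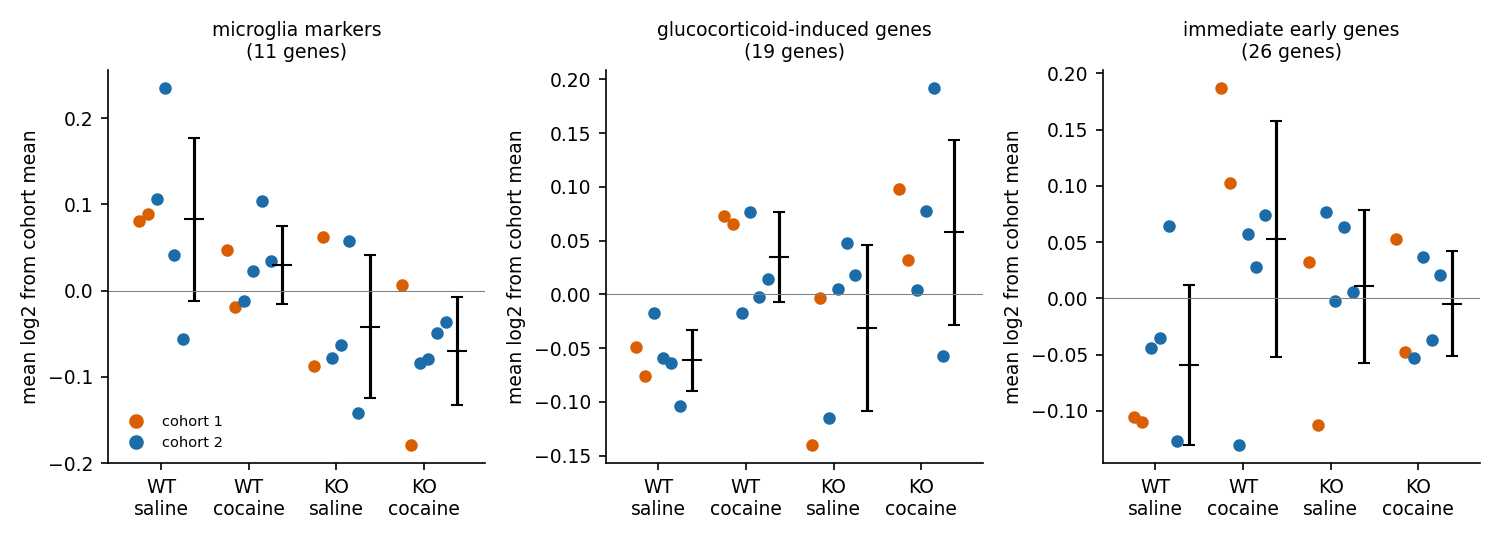
Mean log2 level of 3 gene lists in each pool, relative to the mean of its cohort (vertical axis), by genotype and treatment; points are pools (orange cohort 1, blue cohort 2) and bars the mean ± SD of 6 pools. Microglia markers averaged 0.08 ± 0.09 and 0.03 ± 0.04 in wildtype saline and cocaine pools and -0.04 ± 0.08 and -0.07 ± 0.06 in knockout pools, glucocorticoid-induced genes ran from -0.06 ± 0.03 in wildtype saline to 0.06 ± 0.09 in knockout cocaine pools, and the groups overlapped.

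Tacr1, the substance P receptor, was set to be reported whatever its values. It differed by 0.19 ± 0.09 between knockout and wildtype after cocaine (5 of 6 pools; 0.04 and 0.26 in cohorts 1 and 2; adjusted p = 1.0), or by 0.12 without wildtype cocaine pool 6. After saline it differed by 0.03 ± 0.09, or by -0.02 without knockout saline pool 2, and it did not pass in any contrast. The other 20 lists were not called in any contrast: interneurons, synaptic genes, astrocytes, septum, thalamus and hypothalamus, choroid plexus, clock genes, acetyltransferases and methyltransferases, other histone deacetylases and sirtuins, chaperones, interferon and inflammatory genes, neuropeptides, endothelial and mural cells, genes linked to chronic cocaine, glutamate receptors, tachykinins, actin and spine regulators, class IIa histone deacetylases and MEF2 factors, blood cells, GABA receptors and potassium channels. Their smallest camera adjusted p was 0.0731, for interneuron genes.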

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

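Of the tests given here, the splits of the pools were chosen only after the results were seen; the check of the sample records against Hdac5 was set beforehand.

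For 5 samples (wildtype cocaine pool 5, knockout saline pool 5, knockout cocaine pool 5 and technical array 2 of both cocaine groups) the value table and the bead-level files held another array than the per-array files. Grouped by the per-array files, 0 of these 5 arrays lay nearer the Hdac5 range of the other genotype, which argues against per-array files filed under the wrong genotype. Grouped by the value table, 4 of the 5 did, so the value table and the bead-level files may be filed under the wrong sample. Hdac5 does not tell saline from cocaine, so the treatment of these arrays stays open, and no biological explanation was tested. Without the 3 pools concerned, 14, 20 and 33 probes were called between the genotypes after saline, after cocaine and in the average.

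Single pools lay apart from the other 5 of their group in 9 of 192 sets of values, where chance gives 9.6. The gap to the nearest pool, as a share of the group's range, was 0.836 for Gkn3 in knockout cocaine pool 5 (8.55 against 8.95), 0.669 for Entpd4 in knockout saline pool 6 (6.22 against 6.55) and 0.724 in knockout cocaine pool 3 (6.97 against 6.74), and 0.724 for Sorcs1 in knockout saline pool 2 (9.38 against 9.18). It was 0.641 for Prm1 in knockout cocaine pool 6, 0.699 for Zfp346 in knockout cocaine pool 2, 0.633 for Parp9 in knockout saline pool 6, 0.656 for Cd3d in wildtype saline pool 6 and 0.67 for Phlda3 in wildtype cocaine pool 2. Knockout saline pool 6 was apart in 2 sets, each other pool named here in 1.

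The cocaine effect differed between knockouts and wildtypes in 4 lists by camera: ribosomal protein genes (adjusted p = 0.001469), immediate early genes (0.004011), cortical excitatory markers (0.004183) and oxidative phosphorylation genes (0.04929). With an estimated correlation the adjusted p was 0.952 for each, and no call held. As many lists were called in 23 of 100 splits of the pools, with up to 8 in a split other than the real one, so chance cannot be excluded for their number. Fos, Nrn1, Rps19 and Atp5j had the smallest p in their lists, and none passed when adjusted over the list alone.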

How the results depend on the processing

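Leaving out the 3 pools whose records disagree, leaving each pool out of the list and neighbour tests and the lists in cohort 1 alone and in each cohort with the probes chosen on all pools were tests chosen only after the results were seen. The 17, 24 and 46 probes called between the genotypes kept their sign under each alternative, the fits with 1 pool left out included. The stricter filter tested 11, 14 and 32 of them. In the average over treatments, the brighter Hdac5 probe ran from -3.79 to -2.43 (with 1 pool left out, -2.90 to -2.84). Probes called after saline numbered 11 with median scaling, 0 with the value table, 4 with the own bead summary, 10 with the stricter filter, 9 without a cohort term, 5 in cohort 1 alone, 44 by unadjusted p with a fold and 10 with the value table without the 3 pools. After cocaine they numbered 13 with median scaling, 0 with the value table, 7 with the own bead summary, 14 with the stricter filter, 6 in cohort 1 alone, 41 on all 30 arrays and 62 by unadjusted p with a fold. In the average they numbered 25 with median scaling, 12 with the value table, 22 with the own bead summary, 20 without a cohort term, 26 and 7 in cohorts 2 and 1 alone, 75 on all 30 arrays, 24 by unadjusted p with a fold and 19 with the value table without the 3 pools. Records that place arrays of the other genotype in these groups bear on the losses with the own bead summary, which gave 13, 18 and 36 without the 3 pools. With the value table, leaving out these pools raised the counts from 0, 0 and 12 to 10, 16 and 19, against 14, 20 and 33 with the per-array values. Most of the losses after saline and after cocaine thus went with these records, and a smaller part of those in the average. Technical arrays counted as pools raise counts by construction, and fewer pools or probes lower them; elsewhere the cause was not tested.

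The contrasts with 0 calls by limma (1169, 880, 917 and 1110 probes at an unadjusted p under 0.05 for cocaine in wildtypes, in knockouts, the interaction and cocaine averaged) gave 26, 42, 130 and 9 probes by unadjusted p with a fold, and on all 30 arrays 1 for the interaction and 5 for cocaine averaged. With 1 pool left out, 13 to 18 probes were called after saline, 17 to 23 after cocaine, 35 to 47 in the average, 0 to 1 for the interaction (1 without wildtype saline pool 5), 0 to 1 for cocaine averaged (1 without wildtype saline pool 2 and without pool 6), and 0 for cocaine in wildtypes and in knockouts. The odds ratio near Hdac5 was 11.0 to 23.0 with 1 pool left out, 18.0 within 5 Mb, 12.8 within 20 Mb and 3.3 with unadjusted p. Against 20 list calls in the main setting, the value table gave 11 in all, and an estimated correlation or fry gave 0. With 1 pool left out there were 16 to 27 in all, not each of them among the 20. Between genotypes after saline, the immediate early and oligodendrocyte calls were lost with median scaling (adjusted p = 0.0905 and 0.0539) and without the 3 pools (0.106 and 0.0712), as was the oxidative phosphorylation interaction (0.141 and 0.0706).

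Tacr1, which passed in no contrast, changed sign in several. Between genotypes after saline it was -0.0118 with the own bead summary, -0.0177 in cohort 2 and, with 1 pool left out, -0.0158 (without knockout saline pool 2) to 0.0639. For cocaine in wildtypes it was 0.0412 with the value table, below the median of all probes there (0.07), 0.0185 in cohort 1 and -0.1006 to 0.0085 (without wildtype cocaine pool 6) with 1 pool left out. In cohort 1 it was -0.0599 for cocaine in knockouts and -0.0785 for the interaction. For cocaine averaged it was -0.0207 in cohort 1 and -0.0113 (without knockout cocaine pool 4) to 0.0549 with 1 pool left out. The mean of oligodendrocyte markers between genotypes was 0.0097 in cohort 1, and that of immediate early genes after cocaine in the average -0.0110 in cohort 2; with the probes chosen on all pools they were -0.0097 and -8e-04. Probes dimmer than the median probe, among them Prm1 in most wildtype pools, allow bounds only, and an interaction of 1.2-fold was recovered in 10% of simulated probes.

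With the replicate number as a block, 18, 27 and 52 probes were called between the genotypes after saline, after cocaine and in the average, and 0 in the other contrasts. Pools of the same number were compared by correlating the residuals left after the group and cohort terms, not the intensities themselves. These correlations ran from 0.11 to 0.45 for number 1 and 0.0 to 0.40 for number 2 (medians 0.30 and 0.23). They ran from -0.09 to 0.16 for numbers 3 to 6. In all, 10 of 24 pools were closest, among the pools of the other groups, to a pool of their own number. The numbers of cohort 1 thus went with a shared structure, but the labels give no pairing and not every correlation was over 0.1, so the pools were not fitted as pairs. A block for the chip was not run, since the files name no chip.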

Other observations

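The tests of the genes around Hdac5 other than the exact test of calls within 10 Mb, the tests of Prm1 and the splits of the pools were chosen only after the results were seen.

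Single members of lists that camera did not call passed between the genotypes when adjusted over the list alone, none of them over all probes. Acta2, the smooth muscle actin of vessel walls, was higher in the knockout by 0.47 ± 0.11 (log2, averaged over treatments, 12 of 12 pools) and passed when adjusted over the list alone (adjusted p = 0.00335) but not over all probes (0.0806). The vessel list went both ways: Flt1 was higher by 0.13, and Igf2, Tek and Vwf differed by -0.30, -0.20 and -0.21. Nts, the neuropeptide neurotensin, was higher by 0.60 ± 0.15 in 12 of 12 pools (adjusted p = 0.00811 over the list alone, 0.170 over all probes). Hcrt, a hypothalamic peptide, differed by -0.24 (10 of 12). Gfap, the astrocyte filament, differed by -0.27 ± 0.07 in 12 of 12 pools (adjusted p = 0.0194 over the list alone) and by 0.04 on another probe; it lies within 10 Mb of Hdac5 and so among the genes around the knockout locus. After saline, Slc17a6, a glutamate transporter of thalamic neurons, was higher by 0.89 ± 0.31 and Zic1 by 0.33, each in 6 of 6 pools.

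After cocaine, the clock gene Per2 was higher by 0.30 in wildtypes and 0.34 in knockouts. In the average it was higher by 0.32 ± 0.07 (12 of 12 pools; adjusted p = 5.27e-04 over the list alone, 0.397 over all probes), with 0.64 and 0.17 in cohorts 1 and 2, and by 0.05 on another Per2 probe. Ifit3, an interferon-induced gene, was higher by 0.22 ± 0.06 in 12 of 12 pools (adjusted p = 0.0103 over the list alone) and the endothelial Vwf by 0.30 ± 0.07 in 12 of 12. Opalin, a myelin gene, differed by -0.30 in wildtypes (6 of 6 pools; adjusted p = 0.0281 over the list alone). None of these passed over all probes.

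Called genes gathered around Hdac5: Abca5, Asb16, Krt12, Lsm12, Mpp3, Rapgefl1 and Rdm1 lay within 10 Mb. The share called on other chromosomes predicts 0.338 called genes there, which argues against loss of Hdac5 acting alike on genes wherever they lie as the whole cause. Flanking sequence of another strain, carried with the knockout allele, may contribute (odds ratio 14.8), as may an effect of the altered locus on its neighbours, which was not tested. Sequence differences under single probes are argued against for 3 genes (Krt12, Mpp3 and Fxr2). Other probes of these genes moved the same way at an unadjusted p under 0.05, though that of Fxr2 was not called. Such differences stay open for 4 genes whose other probes did not move (Chd3, Dgke, Lsm12 and Ndel1). They cannot be told apart there from a change in 1 transcript form. Only 7 of the 15 called genes on the chromosome had several kept probes. Sequence differences under the probe thus stay open too for the genes with 1 kept probe: Rapgefl1, Cuedc1, 4933427D14Rik, Asb16, Abca5, Rdm1, Gosr1 and Mif4gd.

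Prm1 was far brighter on every knockout array (10.45 or more, against 6.69 or less on wildtype arrays, in normalized log2 intensity), although it lies on another chromosome than Hdac5. Spermatid genes switched on as a class were argued against by 43 probes of 32 other spermatid genes, whose median difference was 0.0014 (from -0.11 to 0.12), with 0 past the adjusted p by limma and 1 at an unadjusted p under 0.05. Prm1 sequence carried by the knockout allele, such as the polyadenylation segment used in some targeting constructs, is a candidate source: Prm1 differed by -0.1129 ± 0.0789 between cocaine and saline knockout pools, a value that decides nothing. The construct was not described in the sources used here, so this stays open.

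Splits of the pools within cohorts that ignored the groups tested whether chance could give as many calls. For knockout against wildtype, 2 of 100 splits (the real one included) gave as many as the 17 probes after saline (highest other 29). After cocaine 1 gave as many as the 24 (highest other 5), and in the average 2 as many as the 46 (highest other 126). The real counts include probes of the deleted Hdac5 itself (6370139 and 2370035) and of Prm1, whose strong changes ease the adjusted threshold for weaker ones. These are a small part of the 17, 24 and 46, so most of each count lies in other probes. The splits were not repeated without them, so the other called genes were not tested alone. The split with 126 calls set replicate 1 against replicate 2 pools in cohort 1, and so did those with 29 after saline and 49 for the interaction, which points to a structure of the samples by replicate number. With that number as a block, 52 probes were called in the average, 18 after saline and 0 for the interaction, where limma had 917 at an unadjusted p under 0.05 without the block. Where the real count was 0, all 100 of 100 splits gave as many by construction, which tests nothing. The highest other counts were 1, 7, 49 and 4 for cocaine in wildtypes, in knockouts, the interaction and cocaine averaged. At an unadjusted p under 0.05, as many probes came from 66, 44 and 54 of 100 splits between genotypes after saline, after cocaine and averaged. For cocaine in wildtypes, in knockouts, the interaction and cocaine averaged it was 51, 63, 72 and 53, so these counts do not exceed chance.

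For the number of lists, these splits did not exclude chance in any contrast. As many as the real 4, 2 and 2 between genotypes after saline, after cocaine and averaged came from 33, 63 and 58 of 100 splits (highest other 8, 9 and 8). As many as the real 3, 3 and 2 for cocaine in wildtypes, in knockouts and averaged came from 43, 43 and 65 (highest other 7, 8 and 10), and as many as the real 4 for the interaction from 23 (highest other 8). Splits that exchanged groups only between pools of the same replicate number, and so could not part the numbers, gave as many lists in 9, 20, 19 and 20 of 32 splits for saline, cocaine, wildtypes and knockouts (highest other 7, 8, 9 and 9) and in 32, 66 and 70 of 100 for the interaction, the genotype average and the cocaine average (highest other 9, 6 and 8), so chance was not excluded there either. For called probes, only the real split gave as many after saline (1 of 32, highest other 0), after cocaine (1 of 32, highest other 0) and in the average (1 of 100, highest other 19). These counts too include Hdac5 and Prm1, which ease the adjusted threshold for weaker probes. Most of each count lies in other called probes, but the splits were not repeated without Hdac5 and Prm1.

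Single called lists differed in how often a split within cohorts gave as small a p. It was 4, 1 and 1 of 100 for microglia markers after saline, after cocaine and in the average, 2 and 1 of 100 for glucocorticoid-induced genes for cocaine in wildtypes and averaged, and 4 of 100 for ribosomal genes for cocaine in wildtypes. With exchanges within replicate number it was 3 of 32, 1 of 32 and 1 of 100 for microglia markers, 1 of 32 and 3 of 100 for glucocorticoid-induced genes and 1 of 32 for ribosomal genes. The other called lists were matched by 6 or more of 100 splits within cohorts, and these counts were not adjusted for the number of lists.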
